A study of Sus scrofa with 48 samples.

How the data were processed

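RNA sequencing was done on hypothalamus and ileum of pigs (Sus scrofa) on day 7 and day 39, with 48 libraries in 8 groups of 6. Per the labels, piglets were classed as low or high growth by their average daily gain from day 0 to the day of sampling. The labels describe libraries from polyA-selected RNA with a mean RNA integrity number of 7.8, sequenced as paired reads. No litter, sex, pen or batch is given, so none entered the main model. Replicates are separate animals only as far as the labels name separate samples, and if some were not, the p-values would measure a partly technical spread.

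Per the submitters' processing notes, the authors used Trim Galore, kallisto and DESeq2 with the genome build Sscrofa11.1. Versions, the order of the steps, the annotation release and the summing of transcripts to genes are not given in the sources used here. The authors deposited estimated counts per gene for each library, not scaled for library size. Of these values 53% were not whole, as an abundance estimator that shares reads between transcripts gives. Such sharing can split reads between near-identical genes such as the globins, the CYP2D family and the class I and II genes of the pig major histocompatibility complex, so levels of single members are uncertain. The authors also deposited a second table of normalized signal, which was the estimated count multiplied by 1 factor per library, as the ratio of both tables was constant within each library to a relative 4.7e-15. A single cell of it, in hypothalamus day 39 low growth replicate 6, was not a number and was left out. It was used only for an alternative test.

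The tables hold 22924 Ensembl gene identifiers. A RefSeq gene table of the same build gave a symbol for 14894 of them, and 8030 stayed without one. The genes POMC, MC4R, TRH, PYY, LCT, REG3G, IL1B and TNF, which were on the list of genes to be named, were not matched to a symbol here and have no value. Coordinates are those of that table, counted from 1. No library pair was identical, and the highest Spearman correlation between libraries was 0.988 in hypothalamus and 0.99 in ileum.

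Estimated counts were rounded to whole numbers, which moved no value by over 0.5. All genes of a tissue were tested in 1 model over its 24 libraries with 4 groups, so that groups share the estimate of spread. Genes were kept by edgeR's filterByExpr, with a minimum count of 10 and a minimum total of 15. This left 15865 genes in hypothalamus and 15256 in ileum. Library sizes were scaled by TMM. The quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 4 contrasts per tissue were low minus high growth on day 7, the same on day 39, the difference between these 2 growth effects, and day 39 minus day 7 averaged over growth. Standard errors (SE) of log2 fold changes come from that model. CPM is the read count relative to the scaled library size, in the usual unit, given as mean and SD over the 6 libraries of a group, or over the 12 libraries of a day. The common biological coefficient of variation was 0.435 in hypothalamus and 0.349 in ileum.

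Before the data were examined, 51 gene lists were fixed, of which 31 were tested in hypothalamus and 37 in ileum. They cover feeding signals, endocrine peptides, glia and neighbouring brain regions in the first, gut cell types and functions in the second, and general responses in both. A list with at least 4 tested members was tested with camera of limma 3.58.1 against the other genes, at a preset correlation of 0.01 between genes, and adjusted over the lists of the tissue. The same test with a correlation estimated per list, the rotation test fry, and a permutation of growth or day labels on each library's mean log2 CPM over the list stand beside it. Within 1 day that permutation was exact, with a smallest possible p of 0.00216. For the other contrasts it used random shuffles, with a smallest possible p of 1e-04. Counts of members are given over all genes tested and adjusted over the list alone.

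The named genes follow a rule fixed at the same time. For each growth comparison it takes the 8 highest and 8 lowest log2 fold changes among called genes with a symbol and a mean log2 CPM of at least 1, the 6 called genes of lowest p, and up to 4 called members of each list. Where fewer than 5 genes pass, the 5 lowest p are named as not passing. For day 39 against day 7 it takes the 5 highest and 5 lowest and up to 3 called members of each called list, and for the difference of growth effects 4 and 4. Peptide and gut genes fixed by name are given for growth on each day whatever their result, singly or as a range. List members with the lowest p are given as examples. Some genes that the rule takes are not reported here.

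The agreement of growth effects between days was measured as a Pearson correlation across genes of the log2 fold changes of both days. Its two-sided permutation p came from shuffles of the growth labels within each day, on differences of mean log2 CPM.

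The alternatives fixed beforehand were DESeq2 1.42.0, limma voom with quality weights, edgeR with DESeq2 size factors, no and stricter low-count filters, limma on the log2 of the normalized signal plus 1, a fit to the 12 libraries of a day alone, leaving out each library, a covariate of Y-linked genes, and composition covariates. The last were the library means of the myelin and pituitary lists in hypothalamus, and of the smooth muscle and B cell lists in ileum. Some were added after seeing the data. These are a robust quasi-likelihood fit, the label permutation of list means, a fit of the cholesterol synthesis list without ileum day 7 low growth replicate 5, and fits without 3 libraries that stood apart. These 3 were hypothalamus day 39 low growth replicate 3 and ileum day 7 high growth replicates 1 and 5, whose median Spearman correlation with the other libraries of their tissue was 0.848, 0.905 and 0.869. The next lowest were 0.914 in hypothalamus and 0.949 in ileum.

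The tests were run on simulated data with 200 changed genes, drawn from each gene's mean over all libraries of the tissue and from the real library sizes. The members of 1 list were also shifted by 0.5 on the log2 scale and are not counted as false calls. Genes were drawn independently of each other and no library was made to stand apart, so these rates may not carry over to the real data. For ileum on day 7, edgeR recovered 13.4% of genes changed 1.5-fold, 40.3% of those changed 2-fold and 93.9% of those changed 4-fold among 15121 genes, with 2 false calls of 103. DESeq2 recovered 25.4%, 55.2% and 97.0% there, with 23 false calls of 149. For hypothalamus on day 7, edgeR recovered 7.46%, 44.8% and 74.2% among 15759 genes, with 2 false calls of 86, and DESeq2 had 15 false calls of 112. For ileum on day 39 edgeR recovered 8.96%, 41.8% and 89.4% among 15090 genes, and for hypothalamus on day 39 8.96%, 41.8% and 80.3% among 15743 genes. For day 39 against day 7 it recovered 28.4%, 74.6% and 92.4% in ileum among 15101 genes and 32.8%, 58.2% and 89.4% in hypothalamus among 15730 genes. For the difference of growth effects it recovered 0%, 2.99% and 59.1% in ileum among 15107 genes, and 2.99%, 14.9% and 66.7% in hypothalamus among 15745 genes.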

Results

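The data are RNA-seq gene counts of hypothalamus, the brain region that controls feeding and hormone release, and of ileum, the last part of the small intestine, from weaned piglets. In each tissue 24 libraries fall into 4 groups of 6, for low and high growth after weaning on day 7 and on day 39. The total estimated count was 14.2 to 21.1 M (M, mega) per library in hypothalamus, with a median of 16.1 M. In ileum it was 14.4 to 23.2 M, with a median of 16.7 M. Group means of the total lay between 16.1 ± 1.51 M in hypothalamus day 7 high growth and 17.9 ± 3.01 M in ileum day 39 low growth (SD, n = 6). Between 14458 and 15821 genes had a count of at least 10 in the hypothalamus libraries, and between 13942 and 15719 in the ileum libraries. By the series' own account the comparisons ask how gut and brain differ between piglets that grew poorly and piglets that grew well after weaning.

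In hypothalamus on day 7, AVP, the gene of the antidiuretic hormone vasopressin (ENSSSCG00000007163, Sscrofa11.1 chromosome 17, 32581234 to 32583145), had the largest fold difference among the tested feeding and hormone genes fixed by name. Its mean was 93.3 ± 83.8 CPM in low growth and 2490 ± 2930 CPM in high growth (SD, n = 6), a log2 fold change of -4.74 ± 2.0 (SE) that did not pass the test of edgeR (adjusted p = 0.584). The high growth libraries held 3890, 4020 and 6990 CPM in 3 piglets and 3.65 to 18.7 CPM in the other 3, while the low growth libraries lay between 14.5 and 215 CPM. OXT, which encodes oxytocin, went the same way at -3.09 ± 1.89 (adjusted p = 0.72). AGRP, whose peptide drives feeding, was higher in low growth by 3.77 ± 1.73 on the log2 scale (adjusted p = 0.626), at means of only 1.38 and 0.0912 CPM, and NPY, another feeding signal, by 0.48 ± 0.92 (adjusted p = 0.938). The NPY value was 0.21 without low growth replicate 3, 0.26 without low growth replicate 4, 0.31 without high growth replicate 5 and 0.86 without high growth replicate 6. AGRP was above the high growth median in 2 of 6 low growth libraries, at 5.46 CPM in replicate 3 and 2.67 CPM in replicate 6, and its difference was 2.51 without replicate 3. The other 7 named peptide and receptor genes with a value lay between -0.82 for CARTPT and 1.46 for GHRH (adjusted p between 0.832 and 0.989). Without high growth replicate 1 CARTPT was at 2.0 and CRH, the releasing hormone of the stress axis, at 2.57 (-0.43 with it), HCRT turned from 0.71 to -0.090 without low growth replicate 3, and GHRH was at 0.66 without low growth replicate 6.

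The list of cell cycle genes was lower in low growth on day 7 in hypothalamus, with 32 of 34 members below 0, a median log2 fold change of -0.55 and a camera adjusted p of 1.49e-11. Its adjusted p was 0.991 with an estimated correlation. DLGAP5 and KIF11, which act on the mitotic spindle, differed by -1.06 ± 0.29 and -1.03 ± 0.33, and 1 member passed adjusted over the list alone while 0 passed over all genes. Genes of ependymal cells and cilia, which line the ventricles, lay below 0 in 18 of 18 (median -1.03, camera adjusted p = 0.024, and 0.991 with an estimated correlation), among them DNAH5, a motor of cilia, at -1.25 ± 0.53. The cholesterol synthesis list lay below 0 in 20 of 24 members (median -0.32, camera adjusted p = 0.024, and 0.991 with an estimated correlation), and with the myelin and pituitary lists as covariates its adjusted p was 0.0507. In each of both lists 0 members passed over all genes or adjusted over the list alone. The pituitary list itself did not pass (median 0.54, camera adjusted p = 0.426).

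Over all genes, 0 of 15865 passed edgeR's test for low against high growth in hypothalamus on day 7. At an unadjusted p under 0.05 there were 1217, 710 higher and 507 lower, and 19 of 100 splits of the libraries, the real one included, gave as many. DESeq2 called 7 and limma voom 0. Among genes with a symbol the lowest p belonged to E2F4, a regulator of the cell cycle, at 0.47 ± 0.098, ARID3C at 1.71 ± 0.39, PHRF1 at 0.53 ± 0.12, TCOF1, a factor of ribosomal RNA synthesis, at 0.56 ± 0.14, and RAB40C at 0.36 ± 0.092, with adjusted p = 0.549 in edgeR for each. Among the genes that DESeq2 called is TPH2, the enzyme of serotonin synthesis in neurons, at -4.58 (adjusted p = 0.0233 in DESeq2), chosen here after its value was seen. SLC6A4, the serotonin transporter, was at 52.3 CPM or more in day 7 high growth replicates 1 and 3. In the other day 7 libraries it was at 1.09 CPM or less. Whether the TPH2 difference rests on the same libraries was not tested.

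In hypothalamus on day 39, the list of thyroid hormone and tanycyte genes, tanycytes being glia of the floor of the third ventricle, was higher in low growth, with 17 of 21 members above 0, a median log2 fold change of 0.85 and a camera adjusted p of 0.00666. With an estimated correlation the adjusted p was 0.716 for this list and for each of the 8 others that camera called there. SLCO1C1, a thyroid hormone transporter, differed by 4.29 ± 0.93 and CRABP1, which binds retinoic acid, by 7.18 ± 1.66, and 4 members passed adjusted over the list alone while 0 passed over all genes. Genes of glucocorticoid response lay above 0 in 19 of 22 (median 0.21, camera adjusted p = 0.0226), with FKBP5, a chaperone induced by cortisol, at 0.62 ± 0.28. Choroid plexus genes lay above 0 in 13 of 14 (median 1.03, adjusted p = 0.014), and cell cycle genes in 31 of 34 (median 0.36, adjusted p = 6.04e-05). Clock genes lay above 0 in 14 of 17 (median 0.23, adjusted p = 0.00666). MSX1, a developmental regulator in the choroid plexus list, was at 4.11 ± 0.94 and BMAL1, a core clock factor, at 0.83 ± 0.33. Cholesterol synthesis genes lay below 0 in 24 of 24 (median -0.43, adjusted p = 6.79e-08), and myelin genes in 19 of 22 (median -0.18, adjusted p = 2.6e-05). Also below 0 were microglia genes in 14 of 19 (median -0.14, adjusted p = 0.00666) and appetite-lowering signals in 11 of 20 (median -0.13, adjusted p = 0.0269).

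In the low growth group of day 39, replicate 3 stood apart. GAD1, an enzyme of neurons that release GABA, was at 0.713 CPM in it against 18.4 CPM or more in the other hypothalamus libraries, and GAD2, a second such enzyme, at 0.297 CPM against 13.1 CPM or more. Its list means were 3.02 log2 CPM for microglia against 4.50 to 5.33 in the rest of its group, 4.15 for myelin against 5.61 to 10, and 5.37 for cholesterol synthesis against 5.59 to 7.53. They were 0.70 for appetite-lowering signals against 1.42 to 3.7, and 3.23 for choroid plexus against 0.30 to 2.47. The cell cycle mean was 3.04 against 1.73 to 2.61 and the clock mean 5.52 against 4.84 to 5.50. Without that library 4 lists were called by camera, of which 3 were among the 9. These were tanycytes (median 0.40, adjusted p = 9.4e-05), glucocorticoid response (median 0.26, adjusted p = 4.08e-06) and cholesterol synthesis (median -0.24, adjusted p = 9.4e-05). The other was oxidative phosphorylation, lower at a median of -0.090 (adjusted p = 9.4e-05, and 0.25 with that library). For the rest of the 9 the adjusted p was then 0.148 for myelin, 0.149 for cell cycle, 0.0821 for clock and choroid plexus, and 0.856 for microglia and appetite-lowering signals. The medians were then 0.12 for cell cycle, 0.13 for clock and 0.27 for choroid plexus. The medians of myelin (0.044), microglia (0.061) and appetite-lowering signals (0.033) lay above 0 while camera still ranked these lists lower. With the myelin and pituitary means as covariates 6 lists were called, of which 2 were among the 9, namely glucocorticoid response (5.52e-05) and appetite-lowering signals (0.0122). The other 4 were ribosomal proteins, higher (2.69e-07), and ependymal genes (1e-05), endocrine neuropeptides (5.52e-05) and feeding signals (0.000605), lower. The adjusted p was then 0.681 for cholesterol synthesis, 0.257 for tanycytes, 0.247 for choroid plexus, 0.161 for cell cycle, 0.369 for the clock, 0.335 for microglia and 0.921 for myelin, itself a covariate there. For tanycytes, the mean of replicate 3 was 4.16 log2 CPM, and another library of its group had the highest of the tissue, 5.62. Low growth replicate 1 held 56.2 CPM of the tanycyte gene SLCO1C1. The list was not tested without replicate 1, so how far it rests on that library stays open.

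No gene passed in hypothalamus on day 39 either. Of 15865 genes 0 passed in edgeR, 864 had an unadjusted p under 0.05 (56 of 100 splits gave as many), of which 753 were higher. DESeq2 called 18, 16 higher and 2 lower, and limma voom 0. Of the 2 lower, KDM5D is Y-linked, at -23.8 (adjusted p = 0.000178 in DESeq2). Y-linked expression was found in 0 of 6 low growth and 3 of 6 high growth libraries, so this call follows that split of libraries. NPY, which promotes feeding, was at 7.38 ± 10.1 CPM in low growth and 0.695 ± 0.532 CPM in high growth (SD, n = 6), a log2 fold change of 3.40 ± 1.0 (adjusted p = 0.611 in edgeR). AGRP was at 2.94 ± 1.46 (adjusted p = 0.922), GHRH, the releasing hormone of growth hormone, at 2.47 ± 1.26 (adjusted p = 0.938), and AVP at -3.44 ± 1.88 (adjusted p = 0.971). Low growth replicate 1 held 32.3 CPM of AGRP and 27.4 CPM of GHRH, and without it AGRP was at 0.44, GHRH at -1.33 and NPY at 2.39. AVP was at -1.64 without high growth replicate 4 and at -6.71 without low growth replicate 6. The other 7 named peptide and receptor genes with a value had log2 fold changes between -1.61 for CRH and 0.28 for SST (adjusted p = 0.999 for each). Without low growth replicate 2, PMCH, a feeding peptide of the lateral hypothalamus, was at -5.88 (adjusted p = 0.137, and -0.41 with it) and HCRT, which encodes the orexins, at -4.16 (adjusted p = 0.207, and -1.04 with it). Without high growth replicate 1 CARTPT was at -0.097 instead of -1.08, CRH at -0.41 and OXT at -0.70, and without low growth replicate 6 OXT was at -4.1 instead of -1.54. Among genes with a symbol SLCO1C1, SLC17A7, a glutamate transporter of synaptic vesicles, at 7.55 ± 1.66, SAAL1 at 5.58 ± 1.24, PCP2 at 7.61 ± 1.71 and NGFR, a receptor of nerve growth factor, at 4.21 ± 0.95 had the lowest p, with adjusted p = 0.359 for each. Without replicate 3 of low growth the values were 0.37 for SLC17A7, 0.22 for SAAL1 and -0.38 for PCP2, against 3.93 for SLCO1C1, 3.68 for NGFR and 3.67 for NPY. Low growth replicate 1 held 56.2 CPM of SLCO1C1 and 153 CPM of NGFR. Apart from replicates 1 and 3 the group lay at 1.24 to 3.57 CPM for SLCO1C1 and 2.4 to 52.3 CPM for NGFR. High growth means were 0.855 and 3.66 CPM, so both differences rest in part on replicate 1.

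The growth effect on hypothalamus was then compared between days. The cell cycle list had the lowest camera p of the 3 lists called, with 33 of 34 members above 0 for day 39 less day 7, a median of 0.79 and an adjusted p of 3.73e-14, against 0.896 with an estimated correlation for each of the 3. Its member DLGAP5 was at 1.65 ± 0.41. Adjusted over the list alone 2 members passed. The tanycyte list lay above 0 in 19 of 21 (median 0.71) and the choroid plexus list in 13 of 14 (median 1.54), with an adjusted p of 0.0405 for both, and 1 and 2 members passed adjusted over the list alone. For choroid plexus the adjusted p was 0.152 by camera without replicate 3 of day 39 low growth, at a median of 0.70. With the myelin and pituitary covariates it was 0.174 for tanycytes and 0.206 for choroid plexus. Of all genes 0 passed in edgeR, 1233 had an unadjusted p under 0.05, DESeq2 called 1 and limma voom 0. The gene called by DESeq2 was SLC6A4, the serotonin transporter, at 13.8 ± 2.92 in edgeR (adjusted p = 0.627), which rested on 713 CPM in hypothalamus day 39 low growth replicate 3 and on day 7 high growth replicates 1 and 3, at 52.3 CPM in replicate 3 and more in replicate 1. Its value was 6.29 without the day 39 library. Other genes with a symbol and a low p were ARID3C at -2.67 ± 0.56 and SMCHD1, a chromatin factor, at 0.77 ± 0.20 (adjusted p = 0.627 each).

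**Figure D1:**
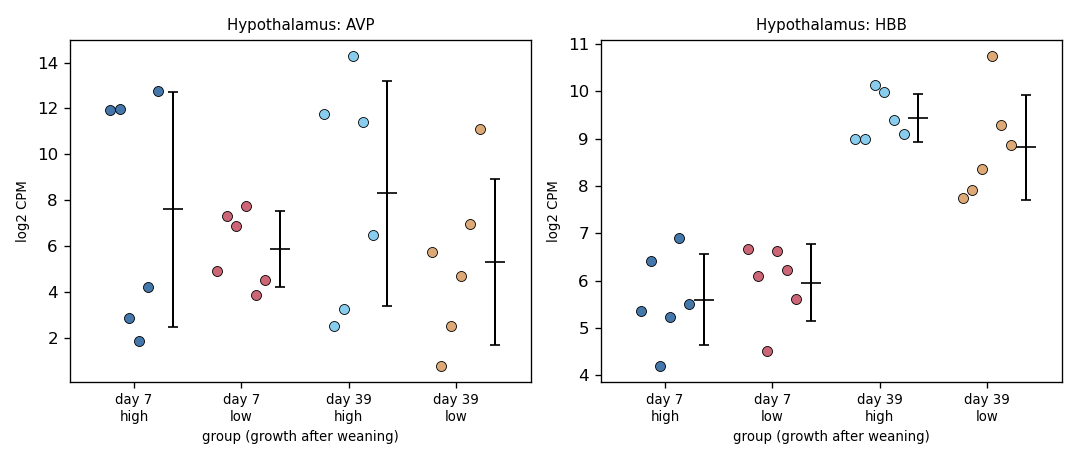
Level in log2 CPM of AVP (left) and HBB (right) in each hypothalamus library (points) by day and growth group, with the mean ± SD of 6 libraries in black. AVP reached 3890 CPM or more in 3 of the day 7 high growth libraries and stayed at 18.7 CPM or less in the other 3, while HBB was above the day 7 median in 12 of 12 libraries of day 39.

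In ileum on day 7, genes of cholesterol synthesis were lower in piglets of low growth. Of 24 members 23 lay below 0, with a median log2 fold change of -0.67, and camera called the list with an adjusted p of 9.57e-24, against 0.0643 with an estimated correlation. HMGCS1, which makes the precursor of mevalonate (ENSSSCG00000016872, chromosome 16, 27936225 to 27957261), was at 166 ± 45.2 CPM in low growth and 343 ± 146 CPM in high growth (SD, n = 6), a log2 fold change of -1.05 ± 0.25 (SE), with 6 of 6 low growth libraries below the high growth median, and -0.64 without high growth replicates 1 and 5. Low growth replicate 5 had the lowest list mean, 4.87 log2 CPM against 5.70 to 6.14 in the rest of its group, and without it the list median was -0.54. SC5D, a late enzyme of the pathway, differed by -0.87 ± 0.22 and IDI1, which acts on isoprenoid units, by -0.93 ± 0.24. Over all genes 0 of the 24 passed, and 15 passed adjusted over the list alone. The adjusted p was 0.0579 in fry, 0.0131 in fry's test for change in either direction, and 0.24 in the exact permutation of list means (unadjusted p = 0.00649), where 1 list alone at the smallest p, 0.00216, could not pass the adjustment.

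**Figure D2:**
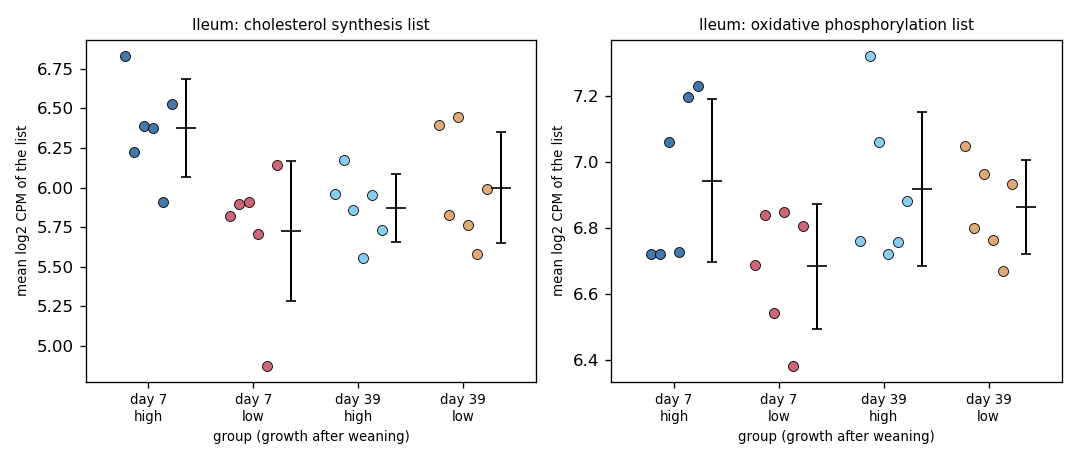
Mean log2 CPM over the cholesterol synthesis list (left) and the oxidative phosphorylation list (right) in each ileum library (points) by day and growth group, with the mean ± SD of 6 libraries in black. On the left the day 7 low growth libraries lay between 4.87 and 6.14, and those of day 7 high growth between 5.91 and 6.53 apart from replicate 1 at 6.83.

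Nuclear genes of oxidative phosphorylation also lay below 0 in ileum of low growth on day 7, in 43 of 44 (median -0.29, camera adjusted p = 5.41e-13, and 0.442 with an estimated correlation), with SDHC of complex II at -0.40 ± 0.13. Nutrient transporters did in 18 of 23 (median -0.30, adjusted p = 8.79e-05, and 0.495 with an estimated correlation), with SLC5A1, the sodium-glucose cotransporter, at -0.80 ± 0.21 and SLC2A2, a glucose and fructose transporter, at -0.91 ± 0.29, against SLC7A8, an amino acid transporter, at 0.88 ± 0.29. Bile acid handling did in 10 of 10 (median -0.62, adjusted p = 0.000342, and 0.442 with an estimated correlation), with SLC10A2, the ileal uptake transporter of bile acids, at -1.41 ± 0.38. Brush border enzymes did in 11 of 13 (median -0.38, adjusted p = 0.000425, and 0.495 with an estimated correlation), with MGAM, which digests starch, at -1.05 ± 0.30. Adjusted over the list alone 0, 8, 2 and 2 members of these lists passed, of which SLC7A8 was higher, and 0 passed over all genes.

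Further lists called lower in ileum on day 7 were interferon-stimulated genes with 32 of 32 below 0 (median -0.63, adjusted p = 2.98e-07) and smooth muscle with 16 of 16 (median -0.53, adjusted p = 0.000425). With an estimated correlation both had an adjusted p of 0.58. So did tight junctions, with 16 of 17 below 0 (median -0.32, adjusted p = 0.00623 by camera). Antioxidant response with 13 of 18 (median -0.22, adjusted p = 0.0201) had 0.442 with an estimated correlation and antigen presentation with 13 of 15 (median -0.26, adjusted p = 0.0477) had 0.602. Lists called higher were B cells and follicles with 16 of 19 above 0 (median 0.24, adjusted p = 4.08e-05, and 0.58 with an estimated correlation) and erythroid genes with 4 of 4 (median 0.70, adjusted p = 0.0196, and 0.23 with an estimated correlation). So were endothelium with 12 of 18 (median 0.21, adjusted p = 0.0201, and 0.646 with an estimated correlation) and amino acid response with 17 of 22 (median 0.24, adjusted p = 0.0211, and 0.457 with an estimated correlation). CTH, an enzyme of cysteine synthesis in the last of these, went the other way at -0.84 ± 0.23.

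Of the day 7 high growth group 2 ileum libraries stood apart. Replicate 1 had a B cell and follicle mean of 2.04 log2 CPM against 6.95 to 7.55 in the rest of its group, and a smooth muscle mean of 8.81 against 6.28 to 7.50. Its mean for interferon-stimulated genes was 9.07 against 6.44 to 8.26 and for brush border 8.89 against 7.52 to 8.02. For bile acid handling it was 6.61 against 4.20 to 5.24 and for cholesterol synthesis 6.83 against 5.91 to 6.53. Replicate 5 had the fewest genes with a count of at least 10, 13942, and 1.79% of its counts on mitochondrial genes. Without both libraries 13 lists were called, of which 10 were among the 14. These were cholesterol synthesis (median -0.59, adjusted p = 1.38e-20), oxidative phosphorylation (median -0.27, adjusted p = 5.61e-11), transporters (median -0.22, adjusted p = 0.0171), bile acid handling (median -0.28, adjusted p = 0.0204), interferon-stimulated genes (median -0.31, adjusted p = 0.0149), smooth muscle (median -0.24, adjusted p = 0.0291) and tight junctions (median -0.17, adjusted p = 0.0149). Antigen presentation (adjusted p = 0.000967), endothelium (0.0268) and erythroid genes (median 1.53, adjusted p = 0.0156) completed the 10, and T cells (0.0169) and glycolysis (0.0101), lower, and the clock (0.0171), higher, were called in addition. Those not called were brush border (median -0.066, adjusted p = 0.175), B cells (median -0.021, adjusted p = 0.52), amino acid response (adjusted p = 0.286) and antioxidant response (adjusted p = 0.14). With the smooth muscle and B cell means as covariates 13 lists were called, of which 6 were among the 14. The adjusted p was then 0.0546 for bile acid handling and antioxidant response, 0.067 for brush border, 0.709 for tight junctions, 0.189 for amino acid response and 0.0957 for antigen presentation. It was 0.831 and 0.997 for smooth muscle and B cells, which are the covariates themselves.

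Of 15256 genes 0 passed edgeR's test in ileum on day 7, and 862 had an unadjusted p under 0.05, 286 higher and 576 lower, where 56 of 100 splits gave as many. Fitted to the 12 libraries of day 7 alone, the count under 0.05 was 351. DESeq2 called 8, 1 higher and 7 lower, and limma voom called 2, both lower. Among genes with a symbol the lowest p belonged to GNLY, a protein of cytotoxic granules, at -1.60 ± 0.35, FAM151B at -1.17 ± 0.27, HMGCS1, PDSS1, which makes the side chain of coenzyme Q, at -0.70 ± 0.17 and GSTO1, a glutathione transferase, at -1.03 ± 0.25 (adjusted p = 0.507 each in edgeR). Both other tools called GNLY (adjusted p = 0.0195 in DESeq2 and 0.0243 in voom), and voom also called KCNN4, a potassium channel, at -0.70 in edgeR (adjusted p = 0.791 in edgeR), chosen here after its value was seen. Among genes fixed by name, SLC15A1, the peptide transporter, was at -0.74 ± 0.29, FABP6, the bile acid binding protein of the ileum, at -0.72 ± 0.35, NTS, which encodes neurotensin, at -0.62 ± 0.28 and CXCL8, a chemokine that draws neutrophils, at -0.72 ± 0.31, with adjusted p between 0.791 and 0.846. FGF19, the hormone by which the ileum reports bile acids to the liver, was at -2.91 ± 1.28 (adjusted p = 0.846), which came from 105 CPM in replicate 1 of high growth and turned to 2.63 without the 2 libraries. Without them SLC15A1 was at -0.45, NTS at -0.19, CXCL8 at -0.32, SLC5A1 at -0.50 and FAM151B at -0.68. The other 10 gut genes fixed by name lay between -0.65 for CLDN1, a tight junction protein, and 0.28 for APOA4, an apolipoprotein (adjusted p between 0.846 and 0.994). Without high growth replicate 1 CLDN1 was at 0.18, without low growth replicate 6 APOA4 was at -0.12, and without both libraries that stand apart SI was at 0.19 instead of -0.40.

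In ileum on day 39 the cytosolic ribosomal proteins lay below 0 in 34 of 34 in low growth, at a median of -0.20 (camera adjusted p = 1.54e-05). With an estimated correlation the adjusted p was 0.997 for this list and for each of the 6 others that camera called there. Brush border enzymes lay above 0 in 11 of 13 (median 0.29), nutrient transporters in 20 of 23 (median 0.20) and cholesterol synthesis genes in 19 of 24 (median 0.13), with an adjusted p of 0.0152 for each, and lipid absorption genes in 14 of 19 (median 0.16, adjusted p = 0.0208), with APOC3, a lipoprotein component, at 1.56 ± 0.71. Myeloid cell genes lay below 0 in 15 of 18 (median -0.16) and interferon-stimulated genes in 21 of 32 (median -0.13), also with an adjusted p of 0.0152. In the 7 lists 0 members passed over all genes or adjusted over the list alone. Without ileum day 7 high growth replicates 1 and 5, which enter the shared model, the adjusted p was 0.0557 by camera for lipid absorption and interferon-stimulated genes, and with the composition covariates 0.0531 for lipid absorption. Of all genes 0 passed in edgeR, and DESeq2 and limma voom called 0. At an unadjusted p under 0.05 there were 162, where 52 of 100 splits gave as many. Fitted to the 12 libraries of day 39 alone, the count was 745. For day 7 it was 351 fitted alone against 862 in the shared model, so these counts do not rank the days. Of genes with a symbol the lowest p on day 39 in the shared model belonged to CRABP1 at 3.31 ± 0.91, RFLNA at -1.63 ± 0.49, ADAMTS3, a protease of the extracellular matrix, at 0.99 ± 0.31, CACNA1S, a calcium channel, at -1.78 ± 0.58 and B3GALT2 at -3.11 ± 1.03 (adjusted p = 0.999 each). SI, which digests sucrose, was at 0.48 ± 0.30, SLC5A1 at 0.34 ± 0.21, MUC2, the main mucin, at -0.12 ± 0.38 and GCG, whose product includes GLP-1, at 0.24 ± 0.29 (adjusted p = 0.999 each). The other 13 gut genes fixed by name lay between -0.725 for FGF19 and 1.0 for APOA4 (adjusted p = 0.999 each). Without low growth replicate 1 MUC2 was at -0.56, FGF19 at -1.77 and APOA4 at 0.22.

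Of the lists that camera called for the difference of the growth effect between days in ileum, cholesterol synthesis had the lowest p. It had 23 of 24 members above 0 for day 39 less day 7, a median of 0.82 and an adjusted p of 1e-21, against 0.104 with an estimated correlation. MSMO1, an enzyme that removes methyl groups from sterols, was at 1.46 ± 0.37, HMGCS1 at 1.36 ± 0.35, CYP51A1, the lanosterol demethylase, at 1.07 ± 0.28, SLC5A1 at 1.14 ± 0.30 and C17orf78 at 1.52 ± 0.41, the 5 of lowest p among genes with a symbol (adjusted p = 0.987 each). Adjusted over the list alone 12 of the 24 cholesterol genes passed, and 0 over all genes. Transporters with 19 of 23 above 0 (median 0.54, adjusted p = 3.65e-06) and brush border with 12 of 13 (median 0.67, adjusted p = 9.23e-06, and a median of 0.28 without day 7 high growth replicates 1 and 5) had 0.424 with an estimated correlation, and oxidative phosphorylation with 40 of 44 (median 0.21, adjusted p = 1.59e-05) had 0.755.

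Another 9 lists were called by camera for the difference in ileum, with an adjusted p between 0.424, for antioxidant response, and 0.787 with an estimated correlation. Above 0 were tight junctions (16 of 17) and smooth muscle (16 of 16) at an adjusted p of 0.00428, bile acid handling (9 of 10) at 0.00644, antioxidant response (13 of 18) at 0.0311 and interferon-stimulated genes (31 of 32) at 0.0327. Below 0 were B cells (17 of 19) at 0.000122, myeloid cells (14 of 18) at 0.00644, ribosomal proteins (26 of 34) at 0.015 and chaperones (16 of 17) at 0.0234. Without day 7 high growth replicates 1 and 5 camera called 19 lists, 10 of them among the 13, and the adjusted p was 0.619 for B cells, 0.186 for myeloid cells and 0.433 for interferon-stimulated genes. With the composition covariates it called 15, 6 of them among the 13, and the adjusted p was 0.218 for bile acid handling, 0.408 for tight junctions and interferon-stimulated genes, 0.196 for chaperones, 0.927 for ribosomal proteins and B cells and 0.98 for smooth muscle. Of 15256 genes 0 passed in edgeR, 459 had an unadjusted p under 0.05, DESeq2 called 2 and limma voom 0. The 2 have no symbol here, ENSSSCG00000030013 at 3.84 and ENSSSCG00000036743 at 2.65 in DESeq2 (adjusted p = 0.428 and 0.453 in edgeR, the lowest of all genes), and were chosen after their values were seen.

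Across genes, the growth effects of day 7 and day 39 had a correlation within the range of shuffled labels in both tissues. Pearson's r across genes, which are not independent replicates, was -0.000532 in hypothalamus and 0.0477 in ileum for the log2 fold changes of edgeR. The labels were shuffled on differences of mean log2 CPM instead, where r was -0.0317 in hypothalamus. On that measure 95% of shuffles lay between -0.506 and 0.527 in hypothalamus and between -0.339 and 0.338 in ileum (permutation p = 0.892 for both). The 2 relations form 1 family, so the Benjamini-Hochberg adjusted p is 0.892 as well. In ileum r of the edgeR values was 0.243 without day 7 high growth replicates 1 and 5 (permutation p = 0.0918 on differences of mean log2 CPM). It was -0.0655 among genes of at least 3 log2 CPM and -0.0405 as Spearman's rho. Leaving out 1 library gave -0.0746 to 0.141 in ileum and -0.11 to 0.0431 in hypothalamus.

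In hypothalamus, red cell genes rose from day 7 to day 39. HBB, the beta chain of haemoglobin (ENSSSCG00000014725, chromosome 9, 4800683 to 4801941), was at 664 ± 431 CPM on day 39 and 63.5 ± 32.9 CPM on day 7 (SD, n = 12), a log2 fold change of 3.39 ± 0.37 (adjusted p = 2.94e-05 in edgeR). ALAS2, the first enzyme of haem synthesis in red cell precursors (chromosome X, 47871519 to 47896041), rose by 3.30 ± 0.31 (adjusted p = 3.84e-06), HBM, another globin, by 3.27 ± 0.42 (adjusted p = 0.000335) and AHSP, the chaperone of alpha globin, by 2.79 ± 0.38 (adjusted p = 0.000736). The fifth called gene, ENSSSCG00000007978, has no symbol here and rose by 3.15 ± 0.35. For each of the 5, 12 of 12 day 39 libraries lay above the day 7 median. All 4 tested members of the erythroid list passed, over all genes and adjusted over the list alone (camera adjusted p = 9.88e-39, 1.8e-05 with an estimated correlation, permutation adjusted p = 0.0031).

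The other 8 lists that camera called for day in hypothalamus were lost with an estimated correlation. Myelin genes lay below 0 in 22 of 22 (median -0.63, adjusted p = 3.25e-11 by camera and 0.661 with an estimated correlation) and cholesterol synthesis genes in 23 of 24 (median -0.47, 4.82e-09 and 0.661). Clock genes lay above 0 in 14 of 17 (median 0.22, 0.000138 and 0.28), with NR1D2, a repressor of the clock, at 0.38 ± 0.098. Chaperones lay below 0 in 16 of 17 (median -0.26, 0.00229 and 0.757). Above 0 were ependymal genes in 18 of 18 (0.0167 and 0.894), tanycyte genes in 18 of 21 (0.0242 and 0.661), endocrine neuropeptides in 18 of 20 (0.0262 and 0.759) and the growth hormone axis in 12 of 15 (0.0319 and 0.661), with GHR, the growth hormone receptor, at 0.75 ± 0.25. With the myelin and pituitary covariates 4 lists were called, of which 1, the erythroid list, was among the 9 and the other 3 were astrocytes, microglia and ribosomal proteins, and without hypothalamus day 39 low growth replicate 3 the growth hormone axis had 0.0577. Adjusted over the list alone 1 myelin gene was lower and 4 clock and 2 tanycyte genes were higher, and 0 passed over all genes. Of 15865 genes 5 rose and 0 fell in edgeR. DESeq2 called 33, 21 higher and 12 lower, and limma voom 20, 11 higher and 9 lower, both with all 5.

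In ileum, genes of T and cytotoxic cells rose from day 7 to day 39. All 28 members lay above 0, at a median log2 fold change of 0.83, 9 passed over all genes and 25 adjusted over the list alone (camera adjusted p = 1.07e-45, 0.000231 with an estimated correlation, permutation adjusted p = 0.0037). CD8A, the co-receptor of cytotoxic T cells (ENSSSCG00000008217, chromosome 3, 57999228 to 58029768), was at 31.2 ± 5.73 CPM on day 39 and 12 ± 3.81 CPM on day 7 (SD, n = 12), a rise of 1.38 ± 0.15 (adjusted p = 2.56e-05 in edgeR). ITGAE, the integrin that holds T cells in the epithelium, rose by 0.97 ± 0.12 (adjusted p = 0.000222) and CD3E, a chain of the T cell receptor complex, by 1.08 ± 0.18 (adjusted p = 0.00321). HBB rose by 1.99 ± 0.32 (adjusted p = 0.00237) and ALAS2 by 2.05 ± 0.39 (adjusted p = 0.00922), 2 of the 4 tested erythroid genes (camera adjusted p = 3.6e-05, 0.00873 with an estimated correlation).

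**Figure D3:**
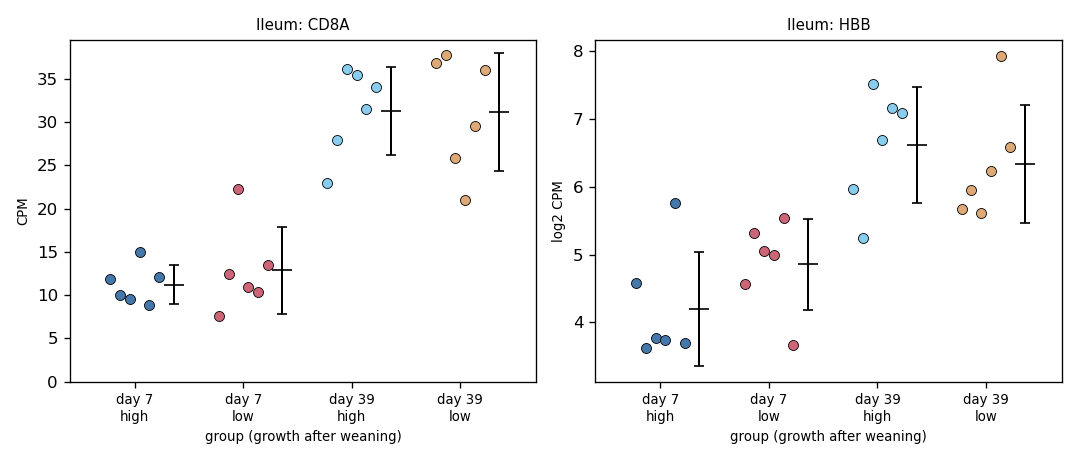
CPM of CD8A (left) and log2 CPM of HBB (right) in each ileum library (points) by day and growth group, with the mean ± SD of 6 libraries in black. CD8A lay between 21 and 37.7 CPM in the day 39 libraries and between 7.58 and 22.3 CPM in the day 7 libraries.

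The genes FABP6, SLC15A1 and APOC3 rose in ileum from day 7 to day 39 as well. FABP6 (ENSSSCG00000017037, chromosome 16, 63297594 to 63303675) was at 4400 ± 1590 CPM on day 39 and 2000 ± 1270 CPM on day 7 (SD, n = 12), a rise of 1.18 ± 0.25 (adjusted p = 0.0235). SLC15A1 rose by 0.96 ± 0.21 (adjusted p = 0.0266) and APOC3 by 2.33 ± 0.52 (adjusted p = 0.0357, and 0.067 without day 7 high growth replicates 1 and 5). In the lists of these genes 1 member each passed over all genes, and adjusted over the list alone 8 of 19 in lipid absorption, all higher, 6 of 23 transporters, 4 higher and 2 lower, and 3 of 10 in bile acid handling. Lipid absorption (camera adjusted p = 3.86e-07) had an adjusted p of 0.371 with an estimated correlation and 0.016 in the permutation. Transporters (0.00367) had 0.608 and bile acid handling (0.00367) had 0.464 with an estimated correlation. Brush border enzymes lay above 0 in 13 of 13 (0.000807, and 0.464 with an estimated correlation), of which 1 passed adjusted over the list alone.

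Among called genes with a symbol and a mean log2 CPM of at least 1, the largest rise was that of ENPP7, an intestinal sphingomyelinase, at 2.68 ± 0.55 (adjusted p = 0.0191). After APOC3 and HBB came CYP2D6, an oxidase of foreign compounds with close relatives in its family, at 1.87 ± 0.31 (adjusted p = 0.00321) and FAXDC2 at 1.82 ± 0.30 (adjusted p = 0.00247). The largest falls were those of TNFAIP6, a hyaluronan-binding protein of inflammation, at -1.76 ± 0.38 (adjusted p = 0.0266) and SPTLC3, of sphingolipid synthesis, at -1.43 ± 0.31 (adjusted p = 0.0266). Next came PI15 at -1.39 ± 0.26 (adjusted p = 0.00866), RIMBP2, a synaptic protein, at -1.38 ± 0.25 (adjusted p = 0.00778) and WNT11, a signal of tissue patterning, at -1.35 ± 0.31 (adjusted p = 0.0459). MFAP5, a microfibril protein of the stroma, fell by 1.04 ± 0.23 (adjusted p = 0.0337) and EGR1, an immediate early factor, by 0.76 ± 0.14 (adjusted p = 0.00886). Without day 7 high growth replicates 1 and 5 the adjusted p was 0.0504 for ENPP7, 0.0615 for TNFAIP6, 0.0653 for SPTLC3, 0.123 for WNT11 and 0.0539 for MFAP5.

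Lists that camera called lower on day 39 in ileum were enteric neurons and glia with 18 of 19 below 0 (3.33e-05, and 0.464 with an estimated correlation) and stroma with 16 of 18 (3.33e-05 and 0.498). So were immediate early genes with 16 of 20 (0.00103 and 0.478) and chaperones with 16 of 17 (0.00103 and 0.64). Further ones were enteroendocrine cells with 15 of 19 (0.00377 and 0.464), cholesterol synthesis with 19 of 24 (0.0117 and 0.705), ER stress genes with 14 of 18 (0.0294 and 0.673) and interferon-stimulated genes with 24 of 32 (0.0448 and 0.827). GCG was at -0.64 ± 0.20 (adjusted p = 0.239). Antigen presentation with 13 of 15 above 0 (0.00203 and 0.464), B cells with 15 of 19 (0.0136 and 0.736) and adipose genes with 8 of 10 (0.0448 and 0.464) were called higher. Without day 7 high growth replicates 1 and 5 the adjusted p was 0.947 for B cells and 0.413 for interferon-stimulated genes. With the composition covariates it was 0.722 for B cells, 0.865 for interferon-stimulated genes, 0.243 for ER stress and 0.0865 for cholesterol synthesis.

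Of 15256 ileum genes 47 rose and 20 fell from day 7 to day 39 in edgeR, so that 70.1% of calls were higher. With limma on the normalized signal 48 rose and 10 fell, or 82.8%. Without day 7 high growth replicates 1 and 5, of which replicate 5 alone moved the count to 101 and replicate 1 alone to 98, 92 rose and 21 fell, and 55 of the 67 genes were among them. DESeq2 called 176 with all 67 among them, limma voom 441 with 58, and the fit with composition covariates 158 with 62.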

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

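The tests for pineal RNA, for another piglet and for the cholesterol list were chosen after those results were seen, and so was a check of blood genes against HBB within groups. The other tests in this part, the splits of the libraries included, were set before their results were seen.

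Among 244 groups of 6 libraries looked at for a single library far from the other 5, 24 had one, where chance gives about 1 in 20, or 12.2. Total counts in M (mega) were far above the rest of the group in hypothalamus day 7 high growth replicate 6 (19.1 M, others 15 to 16.2) and ileum day 7 high growth replicate 6 (22.3 M, others 14.4 to 17.1). On the scale log2(CPM + 1) hypothalamus had a high AGRP in day 39 high growth replicate 4 (2.28), CARTPT in day 7 high growth replicate 1 (8.04), CRH in the same library (4.92), HCRT in day 39 low growth replicate 2 (8.29), PMCH in that library too (9.43) and GHRH in day 39 low growth replicate 1 (4.83). PMCH was low in day 7 low growth replicate 4 (2.69, others 7.63 to 8.24). On the same scale ileum had a low SLC10A2 in day 7 low growth replicate 5 (4.55), a low TJP1 in day 7 high growth replicate 3 (6.14), a high MUC2 in day 39 low growth replicate 1 (10.2), and a high FGF19 (6.70) and SLC15A1 (8.01) in day 7 high growth replicate 1.

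Of list means in log2 CPM, microglia stood low in hypothalamus day 39 low growth replicate 3 (3.02). In ileum day 7 high growth replicate 1, brush border stood high (8.89) and B cells low (2.04). B cells stood low (5.81) and tight junctions high (6.20) in day 7 low growth replicate 3, bile acid handling stood high in day 39 low growth replicate 1 (6.32), smooth muscle low in day 39 high growth replicate 5 (6.53) and cholesterol synthesis low in day 7 low growth replicate 5 (4.87). Antigen presentation stood low in day 7 high growth replicate 5 (6.88) and high in day 39 high growth replicate 2 (8.24).

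The growth effect on day 39 less that on day 7 was tested directly, and camera called 16 lists. The adjusted p was 3.73e-14 for cell cycle and 0.0405 for tanycytes and for choroid plexus in hypothalamus. In ileum it was 1e-21 for cholesterol synthesis, 3.65e-06 for transporters, 9.23e-06 for brush border, 1.59e-05 for oxidative phosphorylation, 0.000122 for B cells, 0.00428 for tight junctions and for smooth muscle, 0.00644 for bile acid handling and for myeloid cells, 0.015 for ribosomal proteins, 0.0234 for chaperones, 0.0311 for antioxidant response and 0.0327 for interferon-stimulated genes. With an estimated correlation 0 of these 16 were called.

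Hypothalamus day 39 low growth replicate 3 may hold pineal gland RNA, among whose markers OTX2, at 908 CPM there, is also 1 of the 14 choroid plexus genes tested. Of 18 pineal markers with a count of 10 or more 17, or 94.4%, were highest in that library, at a median of 59.4 times the highest other library, with RCVRN at 1580 CPM, ASMT at 1540 CPM, CRX at 744 CPM and AANAT at 299 CPM, while MBP of myelin was at 171 CPM against a median of 37300 CPM. Some genes of hypothalamic neurons were nearly absent, with GAD1 at 0.713 CPM (lowest other 18.4), GAD2 at 0.297 (lowest other 13.1), SLC32A1 at 0.119 (lowest other 9.11) and a count of 0 for CARTPT and SIM1, but HCRT at 3.63 CPM was not the lowest (2.45), and the list means of feeding signals (0.918 log2 CPM, others of its group 0.83 to 4.27) and endocrine neuropeptides (2.57, others 2.17 to 5.19) lay within the range of the group, so how much hypothalamus it holds stays open. A library from another piglet than the ileum library of its number is a second candidate explanation. Over genes that go together across tissues, that ileum library ranked 20 of 24 by distance, where 12 of the other 23 pairs ranked 1. Among these genes ENSSSCG00000012178 was at -3.06 log2 CPM in the hypothalamus library and 7.71 in that ileum library, and ENSSSCG00000026430 at -2.07 and 6.59. The Y-linked EIF1AY differed the same way, at -3.06 and 5.28. Others were alike in both, such as ABTB1 at 4.23 and 4.51. This rank therefore restates in part the Y-linked difference given below. In a second form without genes that follow the Y-linked genes, chosen after the first was seen, that ileum library ranked 20 again, where 20 of 23 ranked 1. A library of mostly other tissue could rank low there whatever its piglet, so neither rank is separate support. The pair of this library and the ileum library of its number was the only 1 of 24 unlike in Y-linked genes, which was known when the test was chosen. EIF1AY was at 0 CPM in this hypothalamus library and 37.9 CPM in the ileum library, and KDM5D at 0 and 4.91 CPM. These values argue against 1 piglet for both libraries, with pineal RNA or without. In the other direction, the pair was the best of 6 in its group over 200 variable genes less the Y-linked ones (similarity 0.147). Pineal RNA stays open, and it and another piglet do not exclude each other.

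Cholesterol synthesis genes in ileum on day 7 had a median of -0.667 (SE 0.107 over genes). Each SE in this paragraph treats the genes as independent, which they are not, and holds no spread between animals, so it is too small. The tables argue against 2 technical explanations as the whole cause, namely the 2 high growth libraries that stand apart, without which it was -0.592 (SE 0.0909, 24 of 24 below 0), and the share of muscle and follicles, with which as covariates it was -0.523 (SE 0.0903, 22 of 24 below 0). Low growth replicate 5 stood low for this list (4.87), and the median was -0.539 (SE 0.101) without it and -0.467 (SE 0.0832) without all 3, so these libraries carry a part of the difference. The adjusted p with an estimated correlation was 0.209, 0.274, 0.125 and 0.161 in these fits against 0.0643, and the exact permutation of the list mean gave p = 0.00649, or 0.24 adjusted over the lists, an adjustment that 1 list alone could not pass at the smallest p of 0.00216, so chance stays open. Growth remains an untested candidate explanation among others, such as time since the last meal, for which the labels give no value.

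Erythroid genes rose from day 7 to day 39 in both tissues, and more blood in the day 39 pieces could be the cause. The median of 10 neutrophil and platelet genes was 0.078 (SE 0.126 over genes) in hypothalamus against 3.39 for HBB, and 0.0452 (SE 0.163 over genes) in ileum. The hypothalamus value met the bound set beforehand against blood. That bound was wrong, because these genes lay at only 0.638 to 12.7 CPM on day 7 and did not follow HBB between libraries of a group (slope -0.0755, 95% interval -0.227 to 0.0761, 24 libraries). Blood and a change in red cells between the days can therefore not be told apart. HBB went together between tissues within groups at r = 0.416 (permutation p = 0.0623) and rho = 0.477 (permutation p = 0.0239, 24 pairs at a constant offset in the numbering), and r = 0.572 without the 2 pairs farthest from the median of HBB in hypothalamus, so that of both measures of this relation rho alone lay under 0.05. For T cell genes in ileum, HBB as a covariate left a median of 0.969 against 0.833, with 27 of 28 members above 0 and a camera adjusted p of 1.48e-08, but an adjusted p of 0.498 with an estimated correlation, and since HBB differs between days blood cannot be told apart there either.

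Of 100 splits of the libraries, the real one included, all 100 gave as many genes as the 0 called for growth in each of the 6 growth comparisons, which a count of 0 makes certain and which says nothing about chance. The highest other split gave 2755 genes for hypothalamus day 7, 0 for day 39 and 1303 for the difference, and 2609, 0 and 1363 in ileum. Genes at an unadjusted p under 0.05 were as many in 19, 56 and 19 of the splits for hypothalamus day 7, day 39 and the difference, and in 56, 52 and 56 in ileum, so chance is not excluded for these counts. Splits with over 1000 genes point to some structure of the samples, and what it is was not tested. For day, 3 splits gave 5 genes or more in hypothalamus (highest other 55) and 1, the real one, gave 67 in ileum (highest other 10). Each share of the 100 splits lies under 0.05 taken alone. Neither is adjusted over the 8 comparisons, so chance is not firmly excluded for these numbers of genes. For lists, the splits with as many, the real number and the highest other were 100, 3 and 20 for hypothalamus day 7, 70, 9 and 15 for day 39, 99, 3 and 17 for the difference and 86, 9 and 20 for day. In ileum they were 44, 14 and 24 for day 7, 62, 7 and 18 for day 39, 41, 13 and 22 for the difference and 15, 17 and 22 for day, so chance is not excluded for the number of lists in any of the 8 comparisons.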

How the results depend on the processing

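The fits without the 3 libraries that stand apart, the robust fit and the label permutation of list means were chosen after seeing the data. For 21 results of called genes all 714 values under the alternatives kept their direction, and 85 of them missed the threshold. For named genes not called, 2854 of 2993 values kept their direction, 9 passed the threshold and 0 reversed a call.

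DESeq2 called 7, 18 and 1 genes for hypothalamus day 7, day 39 and their difference, and 8 and 2 for ileum day 7 and the difference, where edgeR called 0. For day it called 33 in hypothalamus and 176 in ileum. Limma voom called 2 for ileum day 7, and for day 20 in hypothalamus and 441 in ileum. For day in ileum the composition covariates gave 158 and the fit without the libraries that stand apart about 1.1e+02, namely 92 higher and 21 lower. In simulated data DESeq2 had more false calls than edgeR in the comparisons where both were run, 23 of 149 against 2 of 103 for ileum day 7, but the cause of these differences in the real data was not tested.

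Leaving out 1 library gave 0 to 0 genes for hypothalamus day 7, day 39 and the difference and for ileum day 39 and the difference, and 0 to 1 for ileum day 7 (1 without low growth replicate 6, ENSSSCG00000022258). For day it gave 5 to 14 in hypothalamus (14 without day 7 high growth replicate 2) and 45 to 101 in ileum (101 without day 7 high growth replicate 5).

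Camera with an estimated correlation, fry and the label permutation called 0 lists for the 6 growth comparisons. Within a day the smallest exact permutation p, 0.00216, lies above 0.05 once adjusted over the 31 or 37 lists if 1 list alone reaches it, so that 0 says little there. For day they called 1, 1 and 1 in hypothalamus and 2, 2 and 3 in ileum, all among those of camera with the preset correlation. For hypothalamus, 4 lists were called on day 39 without replicate 3 of low growth, 3 of them shared, and 4 for day with the composition covariates, 1 of them shared. Genes of a list move together between libraries, with an estimated correlation of 0.401 for cholesterol synthesis in ileum on day 7, far above the preset 0.01, which makes the preset test lenient.

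The correlation of growth effects between days was 0.0431 in hypothalamus without the library that stands apart, and -0.11 (without day 7 high growth replicate 4) to 0.0431 (without day 39 low growth replicate 3) on leaving out 1 library. In ileum it was -0.0655 for genes of at least 3 log2 CPM and -0.0405 as Spearman's rho. Leaving out 1 library gave -0.0746 (without day 7 high growth replicate 3) to 0.141 (without day 7 high growth replicate 5). Without both libraries that stand apart it was 0.243 (permutation p = 0.0918 on differences of mean log2 CPM). The cause was not tested. At these depths and group sizes a 1.5-fold change was recovered in 13.4% of simulated genes for ileum day 7, so smaller growth effects were mostly not detectable.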

Other observations

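The genes in the first paragraph were chosen after their values were seen, and the pairing test was set before its result was seen.

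In ileum, 4 receptor genes outside the fixed list of T and cytotoxic cells rose from day 7 to day 39 as well. TIGIT, an inhibitory receptor, rose by 1.19 ± 0.16 (adjusted p = 0.000327 in edgeR), PDCD1, which encodes PD-1, by 1.31 ± 0.27 (adjusted p = 0.0177), CXCR6, a homing receptor, by 0.94 ± 0.19 (adjusted p = 0.0177) and CCR9, the receptor that guides T cells to the small intestine, by 0.82 ± 0.16 (adjusted p = 0.0148), each in 12 of 12 day 39 libraries above the day 7 median. EPHX2, an epoxide hydrolase, rose by 1.64 ± 0.29 (adjusted p = 0.00545) and AHRR, the repressor of the aryl hydrocarbon receptor, by 0.88 ± 0.16 (adjusted p = 0.0075). CD163, a haemoglobin scavenger receptor of macrophages, and SPP1, which encodes osteopontin, fell. CD163 was at 25.5 CPM on day 39 and 57.7 CPM on day 7 (adjusted p = 0.0193) and SPP1 at 124 and 241 CPM (adjusted p = 0.0371), of which SPP1 had an adjusted p of 0.0585 without the 2 ileum libraries that stand apart.

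A hypothesis is that libraries of both tissues at a constant offset in their numbering come from the same piglet. Over 200 variable genes the mean similarity of such pairs was 0.176, against -0.0628 to 0.0655 for 95% of shuffles within day and growth group (permutation p = 1e-04, the smallest the shuffles can give). Without the Y-linked genes the mean similarity was 0.169. On that measure 19 of 24 hypothalamus libraries matched best with the ileum library at that offset among those of their day and growth group, where chance gives 4. In Y-linked genes 23 of 24 pairs were alike. The exception holds hypothalamus day 39 low growth replicate 3.

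Libraries with Y-linked expression numbered 2 of 6 in hypothalamus day 7 low growth, 1 in day 7 high growth, 3 in day 39 high growth and 0 in day 39 low growth, and 2, 1, 3 and 1 in the same groups of ileum. The list of pituitary genes, 8 tested, had a camera adjusted p of 0.426 for day 7, 0.98 for day 39, 0.47 for the difference and 0.295 for day. Smooth muscle and B cells in ileum had 0.862 and 0.471 for growth on day 39.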
